A study of Mus musculus with 4 samples.

How the data were processed

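Skeletal muscle of 10-week-old mice with free access to food was profiled on 1-colour Agilent mouse 4x44K arrays, per the labels' protocols. The mice had 4 genotypes: wild type (WT), lacking Txnip (thioredoxin-interacting protein, which the labels call TBP-2), ob/ob, and ob/ob lacking Txnip. Each genotype had 1 array, and the 4 arrays lay on 1 slide and came from 1 scan, so no slide or scan effect separates the genotypes. The labels do not say whether an RNA sample came from a single mouse or a pool, which muscle was taken, the strain or sex, or which part of Txnip is deleted. For the ob/ob sample the genotype field and the title are spelled differently, and the title's genotype was used. Per the labels' protocols, tissue was kept in RNAlater, RNA was extracted with a column kit for fibrous tissue, and 0.5 micrograms were labelled with Cy3 together with Agilent spike-in RNA.

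Per the file headers, spot intensity values were produced with Agilent Feature Extraction 9.5.3.1. The processed signal in the deposited scanner files is background-subtracted and corrected for spatial trends within each array, and it is not scaled between arrays, per the file headers. Signals too low to measure carry a surrogate value there. A value table of the same arrays was also deposited by the authors. Before they were deposited its values were turned to log2, as comparison with the scanner signals shows, scaled at the 75th percentile of each array and centred on each probe's median over the arrays, so the table keeps differences between arrays and no levels. How its missing or low values were chosen is not given in the sources used here.

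The main measure was log2 of the processed signal minus each array's 75th percentile over 41174 non-control probes. Spots marked as outliers by the scanner software were left out (78, 62, 59 and 110 spots on the WT, Txnip-null, ob/ob and ob/ob Txnip-null arrays), and the replicate spots of a probe were averaged. A gene was represented by its probe with the highest mean level over the arrays. Probes were named through RefSeq accessions in a table of the GRCm38.p6 assembly (24375 probes), through its symbols (6301) or synonyms (2426), and otherwise kept the name in the files (8072), which gave 27597 genes or named transcripts. Of these, 8942 had more than 1 probe. Probe positions are those of the array annotation, on mm8. No spot was saturated. A pairwise comparison used genes well above background on both arrays. Where a gene was well above background on a single array of the pair, the difference is given as "at least N-fold", with the dim side set at the higher of its own signal and the lowest signal of a probe well above background on that array (11.2, 9.37, 10.8 and 9.13 on the arrays in the order above).

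The arrays had 22675, 24221, 23431 and 23680 probes well above background, and the 75th percentile of the signal was 292, 320.0, 321 and 273. Probes printed 10 times on an array had a median SD between spots of 0.0597, 0.0663, 0.0646 and 0.0691 on the log2 scale. The error given with a log2 difference is a standard error from the signal errors of the scanner software's error model. It covers technical error of the spots and not the spread between mice, and the number of arrays limits the precision.

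The following choices were made before the data were examined: the comparisons, the 2-fold threshold, the alternatives, the gene lists and the rule for the genes named. The 4 comparisons were Txnip-null minus WT, ob/ob Txnip-null minus ob/ob, ob/ob minus WT, and ob/ob Txnip-null minus Txnip-null. With 1 array per genotype these are values without a replicate check, so they carry no p-value. The first pair of comparisons shares no array, and neither does the last pair, so genes 2-fold or more different the same way in both members of a pair were counted beside the number that independent lists would share. The only test the design allows is an additive fit of the Txnip and ob/ob genotypes over the 4 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 1 residual degree of freedom and a Benjamini-Hochberg adjusted p threshold of 0.05. It used genes well above background on at least 2 arrays. Its p-values test the difference fitted for each genotype. The error they use is the departure from additivity between these arrays, moderated by eBayes with variance shared across genes (3.791 prior degrees of freedom). That error need not equal the spread between mice.

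The genes named in each pairwise comparison are those with the 8 largest differences each way that also pass 2-fold under quantile and normexp processing, up to 3 of the largest bounds each way, Txnip and Lep, and up to 4 members of each list. The sets shared by a pair of comparisons name 6 genes each way, the difference of the Txnip effects names 5 each way, and the additive fit names 8 genes per genotype. Genes with clone, predicted or accession names were passed over in the pairwise sets. Genes named outside these rules were chosen after their values were seen.

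The 20 pathway lists were glucose uptake and glycolysis, fatty acid uptake and oxidation, fatty acid and cholesterol synthesis, oxidative phosphorylation, the tricarboxylic acid cycle, mitochondrial and nuclear receptor regulators, insulin signalling, thioredoxin and antioxidant genes, arrestin domain and glucose-sensing factors, atrophy and autophagy, slow fibre, fast fibre, denervation and regeneration, the circadian clock, immediate early genes, endoplasmic reticulum stress and amino acid response, heat shock, inflammatory cytokines, interferon response and extracellular matrix. The 14 cell type lists were markers of adipocytes, brown adipocytes, macrophages, neutrophils, lymphocytes, erythroid cells, endothelium, fibroblasts, smooth muscle, Schwann cells, satellite cells, skin epithelium and tendon, and X and Y genes. Of 536 list entries, 532 were on the array. For each list the median log2 difference of the measured members is given relative to the median of all measured genes. Beside it stands its percentile among 10000 random lists of the same size matched on expression decile, which describes these arrays and is not a test of genotype. Over the 4 comparisons and the means of each pair, 102 of 198 list values lay in the outer 2.5% tails, where lists of unrelated genes would place 10. That figure takes the members of a list as independent and counts the means beside the comparisons they come from. The excess is therefore not a measure of genotype effects.

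The alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median or to 7 spike-in probes, no filter or a stricter filter on dim probes, the median of a gene's probes, the deposited value table, outlier-marked spots kept, thresholds of 1.5-fold and 3-fold, and limma with an intensity trend or with robust=TRUE. Leaving out the genes that stand apart on the WT array was added after the data were seen.

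The steps were tested on simulated data. In the additive fit (16115 genes, 200 of them changed, 5 runs), 2.09% of the genes changed 2-fold were called, 89.9% of those changed 4-fold and 99.1% of those changed 16-fold, and 38 of 673 calls were false. With error-model noise around no difference, for the 15220 genes of Txnip-null minus WT, 67 of 67 genes set at 3-fold passed the 2-fold threshold, as did 4 of 15020 unchanged genes. This noise covers spot error and not the spread between mice, so it does not give the false share among the genes counted below. For Txnip-null minus WT, lists of random members shifted by 0.3 lay in the outer tails in 198 of 200 draws, against 15 of 200 without a shift. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.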

Results

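Messenger RNA of skeletal muscle was measured in mice of 4 genotypes, with 1 array each: WT, Txnip-null, ob/ob and ob/ob Txnip-null. Txnip encodes a protein that binds thioredoxin and restrains glucose uptake, and ob/ob mice lack functional leptin and become obese and insulin resistant. The design asks how loss of Txnip alters the muscle transcriptome in lean mice and in ob/ob mice, and how the ob/ob genotype alters it with and without Txnip. Of 27597 genes, 14908 were well above background on all 4 arrays. With a single array per genotype no difference between a pair of genotypes has a replicate check, and the words higher and lower below describe these arrays.

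Txnip itself had a processed signal of 13209 on the WT array, 868 on the Txnip-null array, 13142 on the ob/ob array and 166 on the ob/ob Txnip-null array. The probe lies on chromosome 3 at 96646629 to 96646688 (mm8). Its level was 16.7-fold lower without Txnip on the lean background (log2 difference -4.06 ± 0.20, SE of the error model) and 67.5-fold lower on the ob/ob background (-6.08 ± 0.21). Another Txnip probe, at 96644567 to 96644741, gave 427 and 561 on the arrays with Txnip and was not well above background on those without it, a difference of at least 49.9-fold on the lean and at least 52.2-fold on the ob/ob background. The labels do not say which part of the gene is deleted, so the signal left on the first probe cannot be assigned to intact transcript. Between ob/ob and WT muscle the probes differed little and in opposite directions, with the brighter probe 1.10-fold lower (-0.14 ± 0.20, turned to the higher side by spike-in scaling) and the other 1.20-fold higher (0.26 ± 0.20). Lep, the leptin gene that carries the ob mutation (chromosome 6, 29023244 to 29023303), had signals of 36.4, 110, 247 and 571 on the same arrays. It was 6.18-fold higher in ob/ob than in WT and 6.09-fold higher in ob/ob Txnip-null than in Txnip-null muscle.

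Loss of Txnip on the lean background went with higher transcripts of tendon and cartilage matrix. Comp, cartilage oligomeric matrix protein, was 32.1-fold higher (log2 difference 5.01 ± 0.22), and the small leucine-rich proteoglycans Fmod and Kera were 24.1-fold and 18.0-fold higher. Tnmd, the tendon membrane protein tenomodulin, was 12.7-fold higher, Chad 11.3-fold, Cilp2 19.5-fold and Angptl7 23.2-fold. All of these were also far above WT on both ob/ob arrays: Comp had signals of 39.0 in WT, 1373 in Txnip-null, 1828 in ob/ob and 2304 in ob/ob Txnip-null muscle. Qprt, which makes the NAD precursor nicotinic acid mononucleotide from quinolinate, was 9.80-fold higher. Among the lower genes, Nmrk2, the muscle nicotinamide riboside kinase, was 9.46-fold lower, from a signal of 36969.6 to 4279. Cth, the cystathionine gamma-lyase that yields cysteine, was 7.78-fold lower, and Epop, a partner of Polycomb repressive complexes, 8.96-fold lower.

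Further lower genes were Fthl17a (12.7-fold), Hoxb9 (9.07-fold), Ccdc146 (8.31-fold) and the Src-family kinase gene Fgr (6.85-fold), all of them bright on the WT array alone. On that array 5 of the 8 spots next to the Fthl17a probe and 3 of the 8 next to the Hoxb9 probe also stood above the other arrays. Among genes well above background on a single array, Ttc25 was at least 27.1-fold, Ecrg4 at least 25.5-fold and Cacnb4 at least 16.1-fold higher without Txnip. Lin28b and Zcchc18 were at least 16.6-fold and 16.3-fold lower.

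In total, 264 of 15220 genes were 2-fold or more higher and 134 lower in Txnip-null than in WT muscle. Of the 264, 98 were also 2-fold or more lower on the WT array than on each of the ob/ob arrays, as were 30 of the 134 in the other direction. Scaled to spike-in probes instead of the 75th percentile, all genes shifted by a median of 0.25 in this comparison, -0.50 in ob/ob Txnip-null minus ob/ob, 0.64 in ob/ob minus WT and -0.12 in ob/ob Txnip-null minus Txnip-null. The split here was then 508 higher and 84 lower. List medians below are relative to the median of all measured genes and do not move with such a shift, while differences smaller than the shift and opposite to it in sign change direction.

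By list, connective tissue, nerve, fat and macrophage markers were higher without Txnip on the lean background. Tendon markers had a relative median of 4.204 (percentile 100 among matched random lists), and extracellular matrix genes 0.56 (percentile 100), with Col1a1 2.77-fold, Timp1 2.09-fold and Postn 2.06-fold higher. Schwann cell markers (relative median 1.05, percentile 100) included Mbp, a myelin protein gene, at 3.40-fold and Prx at 2.22-fold higher. Adipocyte markers (0.80, percentile 100) were led by Lep, 2.76-fold higher, and Adipoq, the adiponectin gene, 2.47-fold higher. Macrophage markers (0.69, percentile 100) included Cd68, 2.35-fold higher, and fibroblast markers had a relative median of 0.41 (percentile 99.99). Fatty acid uptake and oxidation genes were higher (0.33, percentile 100), among them the acyl-CoA thioesterase gene Acot1 at 7.86-fold, whose probe may also bind the near-identical Acot2 (2.62-fold higher), and Angptl4 at 3.004-fold. Smaller medians in the upper tail were those of heat shock (0.16, percentile 99.8), insulin signalling (0.15, percentile 99.9) and slow fibre genes (0.03, percentile 97.7). Oxidative phosphorylation genes had a relative median of -0.23 (percentile 0.0), and none of the 36 was 1.5-fold or more different. Genes of the tricarboxylic acid cycle lay at -0.17 (percentile 4.64), and mitochondrial and nuclear receptor regulators at -0.13 (percentile 5.07). Within glucose uptake and glycolysis (-0.08, percentile 61.1), the glucose transporter gene Slc2a1 was 2.34-fold and Aldoc 2.40-fold lower, while Pdk4, which restrains pyruvate oxidation in mitochondria, was 2.43-fold higher.

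On the ob/ob background, loss of Txnip went with higher Qprt and Aacs and with lower Nmrk2 and Cth transcripts. Qprt was 13.3-fold higher, Aacs, the cytosolic acetoacetyl-CoA synthetase, 10.0-fold, and the metallothionein gene Mt2 6.43-fold, from a family whose members are alike enough to cross-hybridise. Nmrk2 was 7.92-fold lower (-2.98 ± 0.20) and Cth 6.78-fold lower, close to their differences on the lean background. Ppara, the nuclear receptor that drives fatty acid oxidation, was 4.81-fold lower (-2.27 ± 0.21).

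Among the other higher genes, the largest differences were those of Ttc25 (31.5-fold higher) and the calcium channel subunit gene Cacnb4 (24.1-fold higher, with another probe at a log2 difference of 3.54), followed by Katnal2 (10.9-fold) and the protease inhibitor gene Slpi (10.5-fold), both of them dim on the ob/ob array alone. Septin10 was 6.91-fold higher by its brightest probe, but its other probes gave log2 differences of 0.47 and 0.52, and 2 of the 8 spots next to that probe also stood apart on the ob/ob Txnip-null array. Lcmt2 was 17.8-fold, Pard6a, a cell polarity gene, 13.4-fold and Slc25a44, the mitochondrial carrier of branched-chain amino acids, 5.35-fold lower, all of them dim on this array alone, with Slc25a44 at 141 in WT and 136 in Txnip-null muscle. Rnd1 was 4.90-fold lower by its brightest probe, against a log2 difference of 0.13 for its other probe. Of genes well above background on a single array, Olfr782 was at least 29.2-fold, Kctd4 at least 9.92-fold and Cartpt at least 9.91-fold higher. Tsen34, a subunit of the tRNA splicing endonuclease, was at least 284-fold, Samt1b at least 14.6-fold and Olfr960 at least 10.8-fold lower.

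In all, 287 of 15461 genes were 2-fold or more higher and 126 lower in ob/ob Txnip-null than in ob/ob muscle; spike-in scaling turned this split to 83 higher and 826 lower. Adipocyte markers were again higher (relative median 0.99, percentile 100), with Lep 2.72-fold, Adipoq 2.65-fold and Retn, the resistin gene, 2.58-fold higher. Extracellular matrix genes (0.41, percentile 100), fibroblast markers (0.39, percentile 99.99), Schwann cell markers (0.56, percentile 99.98) and macrophage markers (0.32, percentile 99.9) were higher as well. Tendon markers, at 0.40 (percentile 99.2), differed far less than on the lean background. Inflammatory cytokines had a relative median of 0.59 (percentile 100), with the monocyte chemokine gene Ccl2 2.61-fold higher, and of 0.42 (percentile 99.3) on the lean background. Lists of mitochondrial energy metabolism lay on the lower side, while glucose uptake and glycolysis lay on the higher side (0.16, percentile 98.4). Fatty acid uptake and oxidation genes had a relative median of -0.54 (percentile 0.0), with Acot2 2.62-fold and the lipid droplet gene Plin5 2.39-fold lower, against Angptl4 at 5.996-fold higher. Slow fibre genes lay at -0.61 (percentile 0.0), oxidative phosphorylation at -0.19 (percentile 0.0), the tricarboxylic acid cycle at -0.33 (percentile 0.0) with Idh2 2.38-fold lower, and mitochondrial and nuclear receptor regulators at -0.30 (percentile 0.0) with Esrrb 2.40-fold lower. Immediate early genes had a relative median of -0.43 (percentile 0.0), with the stress-induced transcription factor gene Atf3 3.16-fold lower, heat shock genes -0.22 (percentile 0.24), insulin signalling genes -0.14 (percentile 0.66), and atrophy and autophagy genes -0.11 (percentile 1.775, but 0.00573 with the median of each gene's probes), in which Ddit4, an inhibitor of mTOR signalling, was 4.14-fold higher.

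A set of 86 genes was 2-fold or more different the same way with Txnip loss on both backgrounds, and these comparisons share no array. Of these, 55 were higher, against 4.11 for independent lists, and 31 were lower, against 0.909. Beside Qprt and Aacs (5.81-fold on the lean background), the higher set was led by Smoc1, a basement membrane protein gene (6.89-fold lean, 5.84-fold ob/ob), Gys2, the liver form of glycogen synthase (5.23-fold and 5.495-fold), the lysosomal thiol reductase gene Ifi30 (3.61-fold and 3.91-fold) and Tmem40 (7.28-fold and 3.28-fold). It also held Pdk4 (2.43-fold and 2.63-fold), Angptl4, Acaca, the acetyl-CoA carboxylase gene (2.01-fold and 2.80-fold), the Txnip relative Arrdc4 (2.19-fold and 2.33-fold), and Lep, Adipoq and Cfd.

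In the lower set, beside Txnip, Nmrk2 and Cth, stood Kyat3, a kynurenine aminotransferase gene (3.90-fold and 4.37-fold), Epop (8.96-fold and 3.81-fold) and Bcat2, the mitochondrial aminotransferase that opens branched-chain amino acid breakdown (3.65-fold and 3.81-fold). The other Bcat2 probes were lower too, with log2 differences between -1.96 and -0.49 on the lean and between -1.95 and -0.62 on the ob/ob background. Further enzymes of amino acid and ketone body breakdown were in this set: Bckdhb (3.45-fold and 3.48-fold), Dbt (3.23-fold and 3.03-fold), Ivd (3.02-fold and 3.23-fold) and Oxct1, whose signal was 50872 in WT, 15867 in Txnip-null, 39611 in ob/ob and 7735 in ob/ob Txnip-null muscle. Across the 14908 genes on all arrays the log2 differences on both backgrounds had a Pearson r of 0.307; genes are not independent replicates. Arrestin domain and glucose-sensing factors were higher on both backgrounds (relative medians 0.27 and 0.25, percentiles 98.8 and 99.1), as were endoplasmic reticulum stress and amino acid response genes (0.12 and 0.17, percentiles 98.0 and 98.8), with the glutathione-degrading enzyme gene Chac1 2.22-fold and 2.40-fold higher. Thioredoxin and antioxidant genes lay near the median of all genes (0.01 and -0.05, percentiles 92.2 and 11.995).

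**Figure D1:**
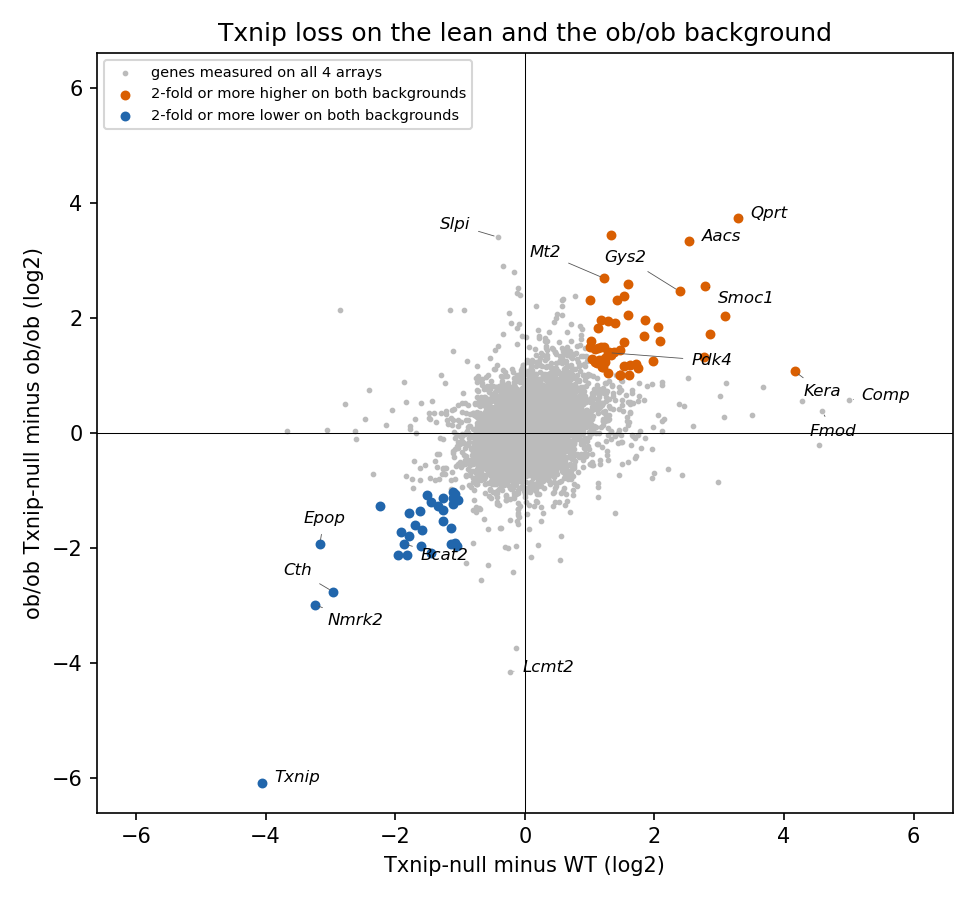
Log2 difference of each gene between Txnip-null and WT muscle (horizontal axis) and between ob/ob Txnip-null and ob/ob muscle (vertical axis), 1 point per gene well above background on all 4 arrays. Coloured points are the 55 genes 2-fold or more higher and the 31 genes 2-fold or more lower on both backgrounds, and tendon genes such as Comp lie far to the right near 0 on the vertical axis.

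**Figure D2:**
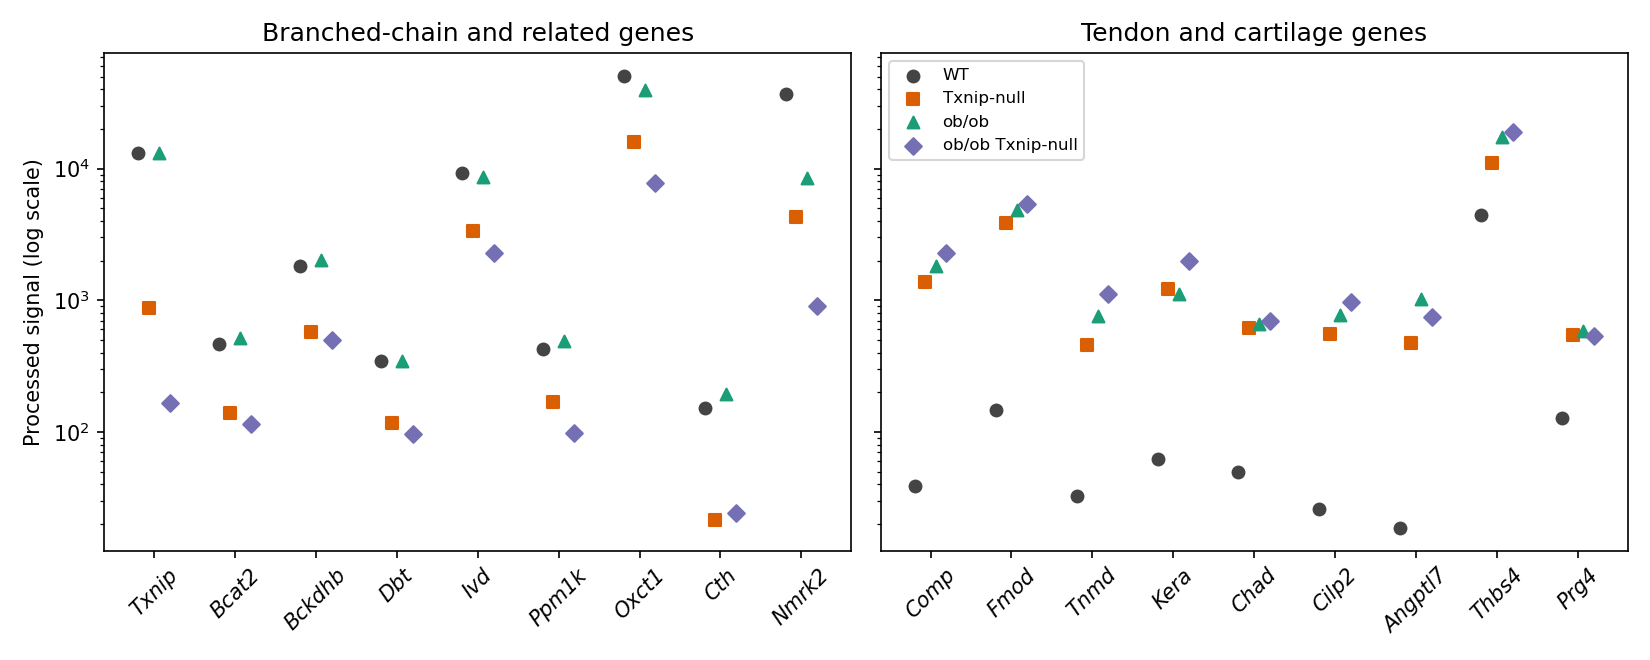
Processed signal (log axis, not scaled between arrays) of selected genes on each of the 4 arrays, 1 point per array. On the left, Txnip and the amino acid and ketone body genes were lower on both arrays without Txnip, and Nmrk2 was also lower with the ob/ob genotype; on the right, the tendon and cartilage genes were lowest on the WT array.

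The ob/ob genotype in the presence of Txnip went with a far higher level of Mss51, a muscle gene for a mitochondrial protein, which was 71.8-fold higher than in WT (6.17 ± 0.20). Its signals were 180 in WT, 1081 in Txnip-null, 14211 in ob/ob and 16791 in ob/ob Txnip-null muscle, so it also stood below every other array on WT. The tendon genes were higher against the same WT array, on which they were lowest, so this is not an independent repeat of their difference with Txnip loss. Angptl7 was 49.7-fold, Comp 42.7-fold, Fmod 30.2-fold, Cilp2 26.8-fold, Tnmd 21.2-fold and Kera 16.4-fold higher. Col22a1, a collagen of the muscle and tendon junction, was 15.7-fold higher. Cish, a cytokine signalling inhibitor that responds to growth hormone, was 19.1-fold lower (-4.26 ± 0.21), and Mup4, a major urinary protein gene, 19.5-fold lower. Cfd, the adipsin gene, was 10.4-fold lower, with signals of 15411 in WT and 1627 in ob/ob muscle. Ighm, the immunoglobulin mu heavy chain gene, was 16.8-fold lower.

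Other lower genes were Fthl17a (11.3-fold), Actr3b (10.8-fold), Cacna2d4 (10.4-fold) and Katnal2 (9.35-fold). Of these, Fthl17a was bright on the WT array alone, where spots next to its probe also stood apart, and Katnal2 was dim on the ob/ob array alone. Mup1, whose close relatives can cross-hybridise, was at least 74.4-fold, Tinag at least 16.02-fold and Lin28b at least 14.4-fold lower, and Col8a2, Six2 and Ecrg4 were at least 24.4-fold, 23.2-fold and 21.0-fold higher. The bounds of Lin28b and Ecrg4 rest on the same WT spots as those given for Txnip loss on the lean background. Altogether 287 of 15088 genes were 2-fold or more higher and 250 lower, of which 98 and 30 stood apart on the WT array; with spike-in scaling the split was 2080 and 72. Interferon response genes were lower (relative median -0.59, percentile 0.0), with Oas1a 2.45-fold and Ifit3 2.35-fold lower. Slow fibre genes were lower (-0.66, percentile 0.0), with the muscle LIM protein gene Csrp3 4.53-fold and slow troponin C, Tnnc1, 2.61-fold lower. Oxidative phosphorylation had a relative median of -0.32 (percentile 0.45), heat shock -0.35 (percentile 1.62) with Hspb1 2.24-fold lower, and thioredoxin and antioxidant genes -0.23 (percentile 1.37) with Gpx3 2.4998-fold lower. Higher lists were tendon markers (4.70, percentile 100), extracellular matrix (0.33, percentile 100), Schwann cell markers (0.54, percentile 99.96), fatty acid and cholesterol synthesis (0.18, percentile 99.7) with Elovl6 2.61-fold higher, insulin signalling (0.18, percentile 99.9) with Tbc1d1 2.98-fold higher, arrestin domain and glucose-sensing factors (0.28, percentile 98.7), atrophy and autophagy (0.11, percentile 99.6) and the circadian clock (0.16, percentile 97.545) with Cry1 2.08-fold higher. Adipocyte markers were split, with 7 of 12 above 0 and 5 below, Cfd among these, and a relative median of 0.16 (percentile 98.3).

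Without Txnip, the ob/ob genotype also went with a high level of Mss51 (18.2-fold above Txnip-null, 4.19 ± 0.20) and with lower transcripts of fatty acid oxidation and slow fibres. Lrmda was 12.4-fold higher, Ddc, the aromatic amino acid decarboxylase gene, 6.61-fold and Lep 6.09-fold. The preadipocyte factor gene Dlk1 was 6.34-fold higher by its brightest probe, with another probe at a log2 difference of 2.36, and stood apart on this array alone. Cfd was 8.68-fold lower. Acot1 was 8.62-fold lower, but it was bright on the Txnip-null array alone, with signals of 127, 1094, 229 and 108 in WT, Txnip-null, ob/ob and ob/ob Txnip-null muscle. Slow fibre genes had a relative median of -1.40 (percentile 0.0), and 8 of 11 were 2-fold or more lower, among them Csrp3 at 4.46-fold, Tnni1 at 3.17-fold and Tnnc1 at 3.16-fold. Fatty acid uptake and oxidation genes had a relative median of -0.85 (percentile 0.0), and 9 of 32 were 2-fold or more lower, among them Acot2 at 3.93-fold, Pdk4 at 3.24-fold and the fatty acid carrier gene Fabp3 at 2.57-fold.

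Further genes were Grik4 (7.45-fold higher, with 2 of the 7 spots next to its probe also apart on the ob/ob Txnip-null array), Septin10 (6.42-fold higher, other probes at log2 differences of 0.06 and 0.52) and Tecrl (6.19-fold higher). Lcmt2 was 18.0-fold, Pard6a 14.1-fold, Tinag 13.2-fold, Lrtm2 8.04-fold and Slc15a5 7.94-fold lower, and Wdfy1 7.95-fold lower by its brightest probe, with its other probes between -2.68 and 1.58 on the log2 scale. Olfr782, Ncan and Kctd4 were at least 33.7-fold, 29.5-fold and 11.4-fold higher, and Tsen34, Ifi27l2b and Ppm1h at least 302-fold, 17.9-fold and 12.9-fold lower. In this comparison 280 of 15618 genes were 2-fold or more higher and 245 lower (215 and 345 with spike-in scaling). Interferon response (-0.64, percentile 0.0), heat shock (-0.65, percentile 0.0) with Hspa1a 2.996-fold lower, immediate early genes (-0.47, percentile 0.0) with Fos 5.28-fold lower, mitochondrial and nuclear receptor regulators (-0.34, percentile 0.0), oxidative phosphorylation (-0.28, percentile 0.0) and the tricarboxylic acid cycle (-0.26, percentile 0.13) were on the lower side. So were thioredoxin and antioxidant genes (-0.19, percentile 0.12), macrophage markers (-0.22, percentile 1.33) and inflammatory cytokines (-0.27, percentile 1.60). Fatty acid and cholesterol synthesis was higher (0.42, percentile 100), with Elovl6 4.53-fold and the fatty acid synthase gene Fasn 3.08-fold higher, as were tendon markers (0.66, percentile 99.96), fast fibre genes (0.17, percentile 99.2), atrophy and autophagy genes (0.21, percentile 99.9), extracellular matrix (0.15, percentile 99.1) and Schwann cell markers (0.22, percentile 97.53).

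With and without Txnip, 65 genes were 2-fold or more higher in ob/ob muscle (4.18 for independent lists) and 76 lower (3.51), in comparisons that share no array. The higher set was led by Mss51, Lep, Ddc (4.12-fold with Txnip), Lrmda (4.13-fold with Txnip), the melanin synthesis gene Dct (4.38-fold and 4.16-fold) and Hoxa11 (11.7-fold and 3.70-fold). It also held the acute phase gene Hp (3.46-fold and 5.73-fold) and the imprinted noncoding RNA genes Meg3 and Rian. The lower set was led by Cfd, Lrtm2 (8.28-fold with Txnip), Wdfy1 (8.51-fold with Txnip, other probes between -3.22 and 1.03 on the log2 scale), Cish (6.28-fold without Txnip), Ighm (5.05-fold without Txnip) and Actr3b (4.95-fold without Txnip). Socs2, another cytokine signalling inhibitor, was 3.02-fold and 2.61-fold lower, and Amd1, which makes a polyamine precursor, 4.003-fold and 2.23-fold lower. Pdk4 and Ucp3, genes of fuel choice, were 3.50-fold and 2.78-fold lower with Txnip. Across genes the Pearson r was 0.438.

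**Figure D3:**
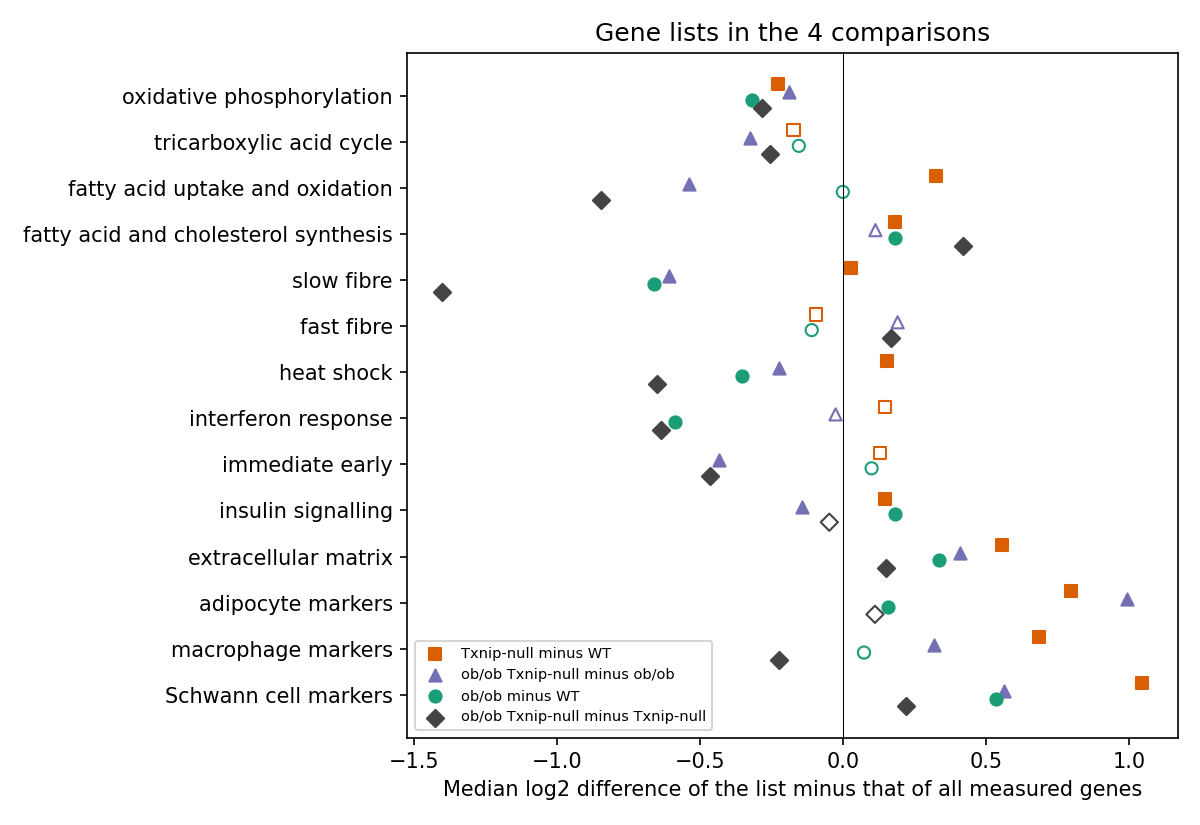
Median log2 difference of 14 gene lists relative to all measured genes (horizontal axis) in the 4 comparisons, 1 symbol per comparison. Filled symbols lie in the outer 2.5% tails of matched random lists and open symbols between them; slow fibre genes reach -1.40 in ob/ob Txnip-null minus Txnip-null muscle.

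The Txnip effect differed by 4-fold or more between the backgrounds for 66 genes, as a difference of differences between single arrays with no test. That count was 8 with the stricter filter, 17 with normexp, 174 with spike-in scaling and 1134 without a filter on dim probes. It was higher on the ob/ob background for Slpi (by 3.81 on the log2 scale), Fthl17a (3.70), Kl, the klotho gene (3.29), Fgr (3.28) and Olfr1101 (3.15, with 2 of the 8 spots next to its probe also apart on the WT array). It was lower for Angptl7 (-4.75), Comp (-4.44), Fmod (-4.22), Lcmt2 (-3.92) and Acot1 (-3.82). Comp was 1.48-fold and Fmod 1.30-fold higher with Txnip loss on the ob/ob background, where spike-in scaling would place Fmod on the lower side. Acot1 was 7.86-fold higher on the lean and 1.80-fold lower on the ob/ob background.

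In the additive limma fit over all arrays, 16 of 16115 genes were called for the Txnip genotype at a Benjamini-Hochberg adjusted p under 0.05, 10 of which rose and 6 of which fell, and 1593 had an unadjusted p under 0.05. The lowest adjusted p, 0.0108 (limma, Benjamini-Hochberg), belonged to Ttc25 (at least 29.2-fold higher), Cacnb4 (at least 19.7-fold higher) and the sperm surface protein gene Adam29, which fell to below background on both arrays without Txnip, by at least 4.25-fold. Lhx8, a homeobox gene, was at least 4.86-fold higher and Akr1d1, a steroid reductase gene, at least 4.16-fold lower (adjusted p 0.0110 for both, limma with Benjamini-Hochberg). The remaining 3 of the 8 genes with the lowest adjusted p have only clone or probe names. Of the genes named above, Qprt (3.52, adjusted p 0.0177), Smoc1 (2.665, 0.0306) and Gys2 (2.42, 0.0353) rose in limma's fit with Benjamini-Hochberg adjustment. Nmrk2 (-3.11, adjusted p 0.0177) and Cth (-2.86, 0.0218) fell in limma's fit with Benjamini-Hochberg adjustment. Each of these differed the same way on both backgrounds. The fit favours such genes, since it takes unequal differences as error, so the agreement adds no support to the calls. Txnip itself had a difference of -5.07 with an adjusted p of 0.0868 in that limma fit after Benjamini-Hochberg adjustment, since its difference was larger on the ob/ob background and the fit takes such a departure from additivity as error.

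For the ob/ob genotype, limma called 51 genes at a Benjamini-Hochberg adjusted p under 0.05, 22 of which rose and 29 of which fell, with 2214 at an unadjusted p under 0.05. At an adjusted p of 0.0186 (limma, Benjamini-Hochberg), Cfd (-3.25) and Tinag (at least 14.5-fold lower) fell. With the same adjusted p of 0.0186 from limma with Benjamini-Hochberg, Ces1f, a carboxylesterase gene, was at least 8.69-fold and Ly6g6e at least 3.27-fold lower. The ubiquitin-like modifier gene Ubd was at least 5.94-fold, the cartilage gene Ucma at least 3.97-fold and Usp50 at least 3.46-fold higher (limma with Benjamini-Hochberg adjusted p 0.0186 for each). Lep rose (2.62, limma with Benjamini-Hochberg adjusted p 0.0241), and Fos (-2.34, 0.0270) and Csrp3 (-2.17, 0.0316) fell. Of the called genes, 11 of the 16 and 30 of the 51 were not well above background on at least 1 array of the lower side, so their fitted differences and p-values rest in part on dim spots. The number of limma calls depended on the processing, with 5 for Txnip and 0 for ob/ob after quantile normalization (2230 at an unadjusted p under 0.05 beside the 0), 7 and 0 without a filter on dim probes (2083 beside the 0), and 585 and 1049 with normexp.

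Fatty acid and cholesterol synthesis genes had relative medians of 0.18 and 0.11 with Txnip loss (percentiles 99.9 and 96.7). Denervation and regeneration genes lay at percentiles 71.5, 41.9, 71.4 and 35.9 in the 4 comparisons in the order used above, although Myod1, a muscle regulatory factor gene, was 2.11-fold and 3.79-fold lower with Txnip loss. Fast fibre genes lay at percentile 65.5, 95.2 and 84.4 in the first 3 comparisons, and circadian clock genes at 65.5 and 55.0 with Txnip loss. Endothelial markers had relative medians of 0.28 and -0.22 with Txnip loss (percentiles 99.4 and 2) and of 0.23 and -0.15 with ob/ob (97.7 and 10.1). Brown adipocyte markers, with 4 of 6 measured, had a relative median of 0.59 on the lean background with Txnip loss (percentile 99.7), where the deiodinase gene Dio2 was 2.92-fold higher, and lay at percentiles 42.4, 56.4 and 23.5 in the other comparisons. The smooth muscle markers lay at 66.6, 10.4, 86.9 and 22.7, although Cnn1 was 2.80-fold and 4.99-fold higher with ob/ob. Lymphocyte markers lay at 68.6, 46.3, 7.675 and 3.42, erythroid markers at 91.7, 69.7, 94.955 and 96.35, satellite cell markers at 73.6, 67.9, 87.55 and 80.1, and skin epithelium markers at 26.8, 39.6, 30.7 and 59.9, each on 5 or fewer measured members. X and Y genes lay at 3.35, 15.85, 44.8 and 47.6, and the 4 Y genes were well above background on every array. Of the 4 probes of Xist, the transcript of the inactive X chromosome in females, a single probe was bright on the WT array (signal 53.8) and a different single probe on the Txnip-null array (80.7), and none on the ob/ob arrays. A lone bright spot of an otherwise dim probe, as at Xist, cannot be told from expression for a gene with a single probe. Only 2 of 8 neutrophil markers were measured, S100a9 and Mpo, and neither was 2-fold different.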

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

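Of the tests in this part, those of additive effects and of muscle share, and the pair that splits the blemish by neighbouring spots, were chosen only after the results were seen, as were the Xist probes and the second tendon list, whose bounds were set before its values were looked at.

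Among the genes named for a difference of the Txnip effects, 1 was 2-fold or more different in opposite directions on the lean and the ob/ob background, and 5 lists lay in opposite outer tails of the random lists, relative to all measured genes. In each of these the difference was not tested. For Kl the Txnip effect was -1.15 on the lean and 2.14 on the ob/ob background, a difference of 3.29 on the log2 scale. Kl was dim, with signals of 44.3 in WT, 21.8 in Txnip-null, 12.3 in ob/ob and 45.9 in ob/ob Txnip-null muscle. The lowest signal well above background on the ob/ob array was 10.8, so this reversal rests on values near the floor. For fatty acid uptake and oxidation the relative medians were 0.33 and -0.54, a difference of -0.86. For slow fibre genes they were 0.03 and -0.61 (difference -0.64, with the lean value near 0 and at -0.05 when not taken relative to all genes), for endothelial markers 0.28 and -0.22 (-0.50), for heat shock genes 0.16 and -0.22 (-0.38), and for insulin signalling genes 0.15 and -0.14 (-0.29).

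Tendon and cartilage genes were lowest on the WT array, with a median log2 difference of 4.68 between the mean of the other 3 arrays and WT over the 4 tendon markers measured. On these arrays the markers departed from separate additive effects of the genotypes: the difference between the Txnip effects had a median of -3.55, with an SD of 1.85 between markers. Comp, Fmod and Tnmd among them had been seen before this test was chosen. It therefore restates the pattern on single arrays and does not decide whether the genotype effects add. A lower share of muscle RNA on the other arrays is argued against by 5 other cell type lists (adipocyte, endothelial, macrophage, smooth muscle and Schwann cell), of which Schwann cell markers had the highest median at 0.92, under the bound of 1.17 set from the tendon median. Less tendon in the WT piece may be the source, but 12 other tendon and cartilage genes gave a median of 0.68, between the 0.5 and 1 set as bounds, so it cannot be told apart from other causes, with Prg4 at 2.07 and Thbs4 at 1.76 and Sox9 at -0.12. An effect in which either genotype alone raises these genes stays open as untested, since each genotype has 1 array.

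A further pattern, among the 14908 genes well above background on all 4 arrays, was 49 cases of a gene 4-fold or more above or below every other array on a single array. Genes below background on some array, such as Tsen34, fall outside this count. A local blemish on the slide is a candidate source for part of it: 12.2% of the probes lay within 2 rows and 2 columns of another of the pattern, 6 probes against 2 at the upper end of the central 95% of random draws. The 6 probes include those of the collagen genes Col11a2 and Col22a1, both low on the WT array. Another Col22a1 probe stood apart the same way (by 3.19 on the log2 scale), while another Col11a2 probe did not (-0.21). The share of 12.2% may thus overstate a blemish. At 6 of the cases, Fthl17a, Olfr1101 and Septin10 among them, 2 or more adjacent spots stood apart the same way, which is 12.2% of them against 1.70% of random probes. At 30 of the cases no adjacent spot did, which argues against a blemish wider than a spot there. A fault of the single spot could not be decided, since only 5 of the cases have another measured probe, and in 60% of these it stood apart too; a difference between the mice stays open as untested.

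Bounds that rest on a single array carry the same limit. Of the 4 Xist probes, 1 was bright on the WT array (signal 53.8) and another on the Txnip-null array (80.7), while the Y genes were measured on every array, so these spots are hard to read as female tissue. The signals of Xist show that a dim probe can stand out on 1 array without the other probes of its gene, which bears on genes given here as at least N-fold different.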

How the results depend on the processing

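Leaving out the genes that stand apart on the WT array was chosen after the data were seen; the other settings were planned. No paired analysis was possible because each genotype had 1 array and the labels carry no replicate numbers. For the same reason no array could be left out of a group, and the additive fit without an array has no residual degree of freedom. Of 163 alternative values of the counts and of Txnip, 84 kept within 1.5 times the main count or within the error; the others follow. For the gene lists, 1654 of 1740 alternative values stayed on the same side of the tails, 55 left the tails and 30 entered them. Of 868 alternative values of named genes, 700 stayed within the error and 168 moved beyond it. Direction changed in 7 of them, those of Fmod, Fthl17a, Lcmt2 and Txnip in comparisons where their differences were small, and in 0 of the 785 with a main difference of 2-fold or more. Counts below are given as higher and lower for Txnip loss on the lean background, Txnip loss on the ob/ob background, ob/ob with Txnip and ob/ob without Txnip, then the genes shared by the Txnip comparisons and by the ob/ob comparisons.

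A threshold of 1.5-fold gave 900 and 500, 1006 and 565, 957 and 1000, 998 and 767, then 361 and 570. A threshold of 3-fold gave 77 and 50, 75 and 38, 74 and 80, 84 and 64, then 24 and 31. Both follow from the threshold itself. With normexp the counts were 79 and 57, 101 and 55, 84 and 106, 98 and 105, then 45 and 54, with 17 genes whose Txnip effect differed 4-fold and a Txnip difference of -5.68 on the ob/ob background; limma with Benjamini-Hochberg called 585 genes for the Txnip and 1049 for the ob/ob genotype. The offset of normexp compresses differences of dim genes. Without a filter on dim probes the counts were 1307 and 899, 1372 and 746, 1185 and 1112, 1367 and 1093, then 354 and 486, with 1134 for the 4-fold difference and 7 and 0 limma calls, the 0 beside 2083 genes at an unadjusted p under 0.05. With the stricter filter they were 60 and 25, 74 and 36, 54 and 73, 53 and 85, then 33 and 42, with 8 for the 4-fold difference and 220 and 370 limma calls, on fewer and brighter genes.

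Spike-in scaling gave 508 and 84, 83 and 826, and 2080 and 72 in the first 3 comparisons, 174 genes for the 4-fold difference, Txnip differences of -3.81 and -6.58, and 101 and 238 limma calls. It shifts all genes of a comparison alike, so the counts follow from its factors; why spike-in and muscle signals differed between arrays was not tested. In the remaining additive fits limma with Benjamini-Hochberg called 5 and 0 genes after quantile normalization (2230 at an unadjusted p under 0.05 beside the 0), 232 and 559 with an intensity trend, 79 for ob/ob with the median of a gene's probes and 32 for ob/ob from the deposited table; the cause was not tested. Without the genes apart on the WT array, 166 genes were higher with Txnip loss on the lean background and 189 with ob/ob in the presence of Txnip, by construction. The relative median of atrophy and autophagy genes with Txnip loss on the ob/ob background, -0.11, turned to 0.00573 with the median of a gene's probes; the cause was not tested. Signal over background limits the fold of dim genes: the lowest signals well above background were 9.13 to 11.2.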

Other observations

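The list of branched-chain amino acid catabolism genes and the genes of limb position were chosen after results were seen, and so were the tests of dilution, of the pathway members outside the set shared by both backgrounds and of those outside the segment around Txnip; the other tests in this part had their bounds set before their values were looked at.

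Genes of branched-chain amino acid breakdown were lower with Txnip loss on both backgrounds, with median log2 differences over all 24 members of -0.75 on the lean and -0.76 on the ob/ob background (-0.68 and -0.79 relative to all measured genes). Of the 24, 8 were 2-fold or more lower on the lean background and 9 on the ob/ob background. The members run along the pathway from Bcat2 and the branched-chain dehydrogenase genes Bckdhb and Dbt, with Bckdha 1.54-fold and 1.71-fold lower, to Ivd, Acadsb (2.74-fold and 2.31-fold), Mccc2 (1.69-fold and 2.59-fold), Pcca (1.74-fold and 2.53-fold) and Aldh6a1 (2.11-fold and 1.75-fold). Ppm1k, the phosphatase that activates the dehydrogenase, was 2.73-fold and 4.26-fold lower. With the ob/ob genotype the median log2 differences of the same list were -0.17 and -0.15 (-0.13 and -0.19 relative to all measured genes). Klf15, a transcription factor known to promote branched-chain amino acid breakdown in muscle, was 2.08-fold and 1.49-fold lower with Txnip loss.

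Dilution of muscle RNA by other cells is argued against, since the pathway median over both backgrounds lay below that of fast fibre genes by more than 0.2, with a gap of -0.78. That comparison does not cover a wider fall of oxidative genes. On the ob/ob background the relative medians of slow fibre (-0.61) and fatty acid oxidation genes (-0.54) were low too, beside -0.79 for the pathway. On the lean background they were 0.03 and 0.33, beside -0.68. Oxidative phosphorylation genes lay at -0.23 on the lean and -0.19 on the ob/ob background. The 19 members not looked at before had a median of -0.70 at percentile 0.0 of matched random lists, which decides nothing by itself, since 3 of them (Acadsb, Dbt and Ivd) belong to the set that prompted the list; the 16 others not looked at before and outside that set had a median of -0.62 at percentile 0.0, which argues against a pattern carried by the set alone. A passenger segment kept from the line in which Txnip was deleted might account for 1 of the 16 members that were 1.5-fold or more lower, Dbt, which lies within 20 Mb of Txnip, and this cannot be told apart from a Txnip effect. The other 15 members lie outside that span, so they are not carried in it. Whether a variant within the segment acts on genes elsewhere was not tested. A lower expression of the pathway in the absence of Txnip stays a hypothesis, found and tested on the same arrays and with 1 array per genotype.

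Of the genes 2-fold or more different the same way with Txnip loss, 3 of 84 placed lay within 20 Mb of Txnip (3.57%), against 358 of 14726 others (2.43%), with a two-sided Fisher's exact p of 0.461. For the ob/ob genotype 0 of 140 lay within 20 Mb of Lep, against 171 of 14670 others (1.17%), with a two-sided Fisher's exact p of 0.415.

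Of 25 genes that mark position along the limb and body and were measured on all 4 arrays, 3 were 2-fold or more different the same way in both ob/ob comparisons, namely Hoxa11, Hoxd10 and Hoxc6, and 22 were not. Of all 14908 genes measured on the 4 arrays, 65 were higher and 76 lower in that way, a smaller share. The shares cannot be weighed against each other, since the list was chosen after results were seen and holds Hoxa11, already named among the leading genes of that set. Hoxa11 had signals of 30.2 in WT, 93.0 in Txnip-null, 387 in ob/ob and 293 in ob/ob Txnip-null muscle. Hoxa13 was not well above background on the WT and Txnip-null arrays and had signals of 24.8 and 15.1 on the ob/ob and ob/ob Txnip-null arrays. Hoxd10 had signals of 24.0, 46.2, 84.9 and 102 in the same order of arrays, Hoxc6 of 315, 283, 132 and 105, and Pitx1 of 135, 167, 62.0 and 83.7. Smaller differences the same way in both ob/ob comparisons were those of Hoxd8 (log2 0.62 and 0.81) and Hoxd9 (0.65 and 0.63), which were higher. Hoxc5 (-0.95 and -1.03) and Hoxb3 (-0.47 and -0.85) were lower. Hoxc9, Hoxc10 and Tbx15 were less than 1.5-fold different in each comparison. The labels do not say which muscle was taken, and the cause of these differences was not tested.

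Genes other than Kl moved 2-fold or more in opposite directions with Txnip loss on the lean and the ob/ob background. With Kl included, 2 genes were higher on the lean and lower on the ob/ob background, against 2.05 for independent lists. In the other direction there were 4, against 1.82. Such small counts do not set these genes apart from unrelated lists. Acot2 was 2.62-fold higher and then 2.62-fold lower, Ch25h, which makes 25-hydroxycholesterol, 2.18-fold higher and 2.16-fold lower, and the protease gene Htra4 2.45-fold lower and 2-fold higher. These differences were not tested.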
